A study of Mus musculus with 6 samples.

How the data were processed

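Single-colour Agilent arrays were available for 6 mouse livers, 3 from control mice and 3 from mice that drank water with MC-LR. Groups and replicate numbers came from the sample titles, and the labels say that the livers came from independent mice. Per the labels, total RNA was amplified and labelled with Cy3. The scanner files hold spot intensity values from Agilent Feature Extraction 10.7, per the submitters' processing notes. Per the file headers, the processed signal intensity is background-subtracted and detrended within the array, with dim spots set to a surrogate value, and the mean and local background intensity columns are uncorrected. The deposited value table holds log2 values that the authors normalized between arrays by the quantile algorithm of GeneSpring, per the series' design text. Each of its columns correlated at r of 0.9982 to 0.9999 with log2 of its own array's processed signal, with a median of 5.94 in each column, and its values differed from those computed here by a median below 0.002, so its scale is log2, it is not centred by gene, and a higher value means more signal. It was used as an alternative.

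For the comparison, processed signals under 1 were set to 1, log2 was taken, spots with outlier flags were left out, replicate spots of a probe were averaged, and the arrays were quantile normalized over probes that were not controls, as the design text states for the study. Of 41174 such probes, 30 had no value left on some array. A probe was kept if it was well above background on all 3 arrays of at least 1 group, which left 28487 probes. Probes were named through RefSeq accessions in a table of the GRCm38.p6 assembly (27668 probes), then through symbols or synonyms (6060), and otherwise kept the name in the file (7446). A gene was represented by its probe with the highest mean signal, which gave 18901 genes, 6551 of them with more than 1 passing probe. Of 48 other probes of genes named in the text or eligible for naming, 40 differed in the same direction as the probe used, and among the opposite ones were probes of Ppp2ca, Gclm, Igbp1, Nfkb1 and Rps28. Probe coordinates are those of the files, whose headers name mm9. Between 64.9% and 73.7% of spots were well above background per array. Where a probe was not well above background on any array of a group, the difference is given as a bound, the mean of the brighter group against the mean of, per array, the higher of the probe's own value and the lowest value among probes well above background (means of normalized log2 values).

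Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, with 4 residual and 2.05 prior degrees of freedom), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A total of 32 pathway lists and 15 lists of cell type or zone markers, written from textbook knowledge before the data were examined, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 47 lists, and with camera at an estimated correlation and fry as alternatives. A list needed at least 5 measured members, and members with no probe under their name are not analysed here. Counts adjusted over the list alone use the same p-values, adjusted within the list. The pairing of the replicate numbers was tested as an alternative because the labels give both groups the numbers 1 to 3.

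Genes are named by a rule set at the same time: in each direction up to 12 genes with the largest difference among those past the adjusted threshold, with the 3 arrays of each group apart, well above background on all 3 arrays of the higher group, and with a symbol that is not a clone or accession name. With fewer than 5 such genes in a direction, the list was filled to 8 with genes at an unadjusted p under 0.05, which are said not to pass. For each list described, up to 4 members past the adjusted threshold or, if none, the 2 with the smallest p are given as values, and 8 targets and transporters of MC-LR are always given. Genes outside this rule are marked as named after their values were seen. Some list members are not reported here.

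Other settings were 75th percentile and median scaling, normexp background correction (offset 50) followed by quantile normalization, the deposited log2 values, no filter and a strict filter on dim probes, the mean of a gene's probes, every probe as its own feature, slide as a fixed or random block, slide 2 alone, the replicate number as a block, eBayes with trend and robust, array weights, other thresholds, and each array left out in turn. Slide comes from the array header and coincides with the scan. The steps were tested on simulated data of the same 18901 genes, with normal noise at each gene's own mean and spread, in 20 runs of 3 against 3 with 200 changed genes. Of genes changed by 1 on the log2 scale 48.1% were recovered, and of genes changed by 2, 83.2%. Of the calls, 5.54% were of unchanged genes. A list of 41 genes shifted by 0.5 was called in all 20 runs, and on average 0 of the 46 other lists were called, with noise drawn independently for each gene. That shift exceeds the median difference, in either direction, of every called list but the clock list, so smaller shifts were not tested. The rate of false list calls does not carry over to genes that move together. In the real arrays, splits other than the real one called 7 to 28 lists.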

Results

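Gene expression was measured in the livers of 6 male BALB/c mice, 3 that drank water with microcystin-LR (MC-LR) and 3 that drank sterile water. MC-LR is a cyanobacterial toxin that inhibits protein phosphatases 1 and 2A and enters hepatocytes through organic anion transporters. Exposure began at 6 weeks of age and lasted 12 months at 100 µg/L. Each liver was hybridised to its own single-colour Agilent mouse array, and the labels describe the 3 livers of a group as coming from independent mice. Of the spots that were not controls, 64.9% to 73.7% lay well above background on each array, and 0 were saturated. The number of arrays limits the precision. Controls 1 and 2 were on slide 1, and control 3 and the 3 MC-LR arrays were on slide 2, so slide 2 alone held both groups. All pairs of arrays correlated at r = 0.982 to 0.994 across probes. The first principal component (36.5% of the variance) placed controls 1 and 2 apart from control 3, and the second (31.4%) placed the controls apart from the MC-LR arrays.

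The series' title asks which liver genes are expressed differently after exposure to MC-LR. Lingo4, which encodes a leucine-rich repeat and immunoglobulin domain protein, rose 6.67-fold, from 6.15 ± 0.16 in controls to 8.88 ± 0.05 with MC-LR (normalized log2 signal, mean ± SD, n = 3 per group; adjusted p = 0.00289, limma). Cst10, a member of the cystatin family of protease inhibitors, was well above background on all 3 MC-LR arrays and on 0 of the 3 control arrays, and was at least 3.67-fold higher with MC-LR (adjusted p = 0.000239). The third gene to pass, 2610034B04Rik, was also not well above background in any control (adjusted p = 0.0112) and is named because so few passed, after its values were seen. Its MC-LR signal lay too near the background level to give a fold. At an unadjusted p under 0.05 by limma there were 2434 genes (1422 higher and 1012 lower), where chance alone would give 945 on average. Other splits of the 6 arrays into 3 and 3 gave 121 to 2508 such genes, so the excess over 945 is not particular to the real groups. In all, 3 of 18901 genes rose and 0 fell at an adjusted p under 0.05 by limma. The count was 15 with slide as a block, 0 within slide 2 (limma, 2308 at an unadjusted p under 0.05), 50 without control 3 and 1 without MC-LR 1. Without control 3 both controls left are on slide 1 and all MC-LR arrays on slide 2, so slide and group then coincide. Of genes at an unadjusted p under 0.05 with slide as a block, 1511 were higher and 1533 lower. For Cst10, with controls near the floor of the scale, the log2 difference under normexp was 0.53 and the call ended (adjusted p = 0.1003). It also ended under 75th percentile scaling (adjusted p = 0.0586), median scaling and within slide 2 (range over its alternatives 5.95e-05 to 0.143). In these 3 settings the fitted log2 differences, which are no folds as the controls were near the floor, were 3.86 ± 0.30, 3.90 ± 0.31 and 4.15 ± 0.16 (SE) against 4.11 ± 0.10, so the difference stayed while its SE grew, and within slide 2 only 1 control was left. For Lingo4 the difference under normexp was 1.72, and the call ended without MC-LR 1 (adjusted p = 0.0643) and within slide 2 (range over the settings that leave the mice unpaired 0.00208 to 0.143), where the differences were 2.71 ± 0.14 and 2.70 ± 0.14 against 2.74 ± 0.11. All 3 genes passed with slide as a block (adjusted p = 0.0117 for Cst10, 0.0353 for Lingo4 and 0.0388 for 2610034B04Rik). The call of 2610034B04Rik ended under the same scalings, normexp (adjusted p = 0.429) and eBayes with trend and robust, within slide 2, and without control 1, control 2, MC-LR 1 or MC-LR 3 (range 0.00356 to 0.429).

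Other large differences had the 3 arrays of a group apart from the other 3 and did not pass the adjusted threshold. Thrsp, a regulator of lipogenesis, stood at 10.84 ± 0.61 in controls and 14.27 ± 0.47 with MC-LR (log2 signal, mean ± SD, n = 3; adjusted p = 0.147, limma). Igfbp1, an insulin-repressed binding protein for insulin-like growth factors, stood at 13.88 ± 0.75 and 11.51 ± 1.07 (adjusted p = 0.271). Tubb2a, a beta-tubulin, stood at 14.72 ± 0.29 and 12.76 ± 0.49 (adjusted p = 0.156). Values on the higher side also came from Ciart, Usp2 and Wee1, described with the circadian genes, from Btbd35f1, at least 4.41-fold higher, and from Olfr677, with a log2 difference of 3.83. Btbd35f1 was not well above background in any control. Olfr677 was well above background on 1 of the 3 control arrays. Chrm3 and Ube2u, named next, were well above background on 1 and 2 of the 3 MC-LR arrays. On the lower side, Arntl, Noxa1, Glipr2, Chrm3, Ube2u and Rasal1 differed by -3.02 to -2.10 on the log2 scale, with adjusted p from 0.243 to 0.304. Under normexp the values were 0.71 for Btbd35f1, 1.21 for Olfr677 and -2.17 to -0.50 for these 6 lower genes. The lower 6 differed with slide as a block by -1.83, -0.97, -2.95, -1.14, -1.49 and -3.10 in the order named, Igfbp1 by -1.59, Tubb2a by -1.73, Thrsp by 2.73 and Olfr677 by 5.01. Btbd35f1 passed with slide as a block (adjusted p = 0.0353), in effect the MC-LR arrays against control 3, as did Usp2 and Wee1. Without control 3, where slide and group coincide, Btbd35f1 (adjusted p = 0.00213), Thrsp (adjusted p = 0.0376) and Chrm3 (adjusted p = 0.0413) passed. Their ranges over alternatives were 0.00213 to 0.615, 0.0176 to 0.615 and 0.0295 to 0.671. The probes behind these values, in mm9 coordinates per the file headers, lie for example at chromosome 3, 94208322 to 94208381 (Lingo4), chromosome 2, 149235773 to 149235832 (Cst10), and chromosome 7, 104565562 to 104565621 (Thrsp). No exon or UTR annotation of that build was used here.

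Genes of the circadian clock list were higher as a group with MC-LR, with a median log2 difference of 1.09 over the 22 measured members (camera, adjusted p = 1.18e-05). The adjusted p = 0.647 with an estimated correlation. Usp2, a clock-controlled ubiquitin protease, stood at 6.55 ± 1.26 in controls and 10.97 ± 0.09 with MC-LR (log2 signal, mean ± SD, n = 3), a difference of 4.41 ± 0.60 (SE). Wee1, a clock-controlled cell cycle kinase, was well above background on all 3 MC-LR arrays and on 0 of the controls, at least 4.24-fold higher. Over all genes tested, 0 members passed (adjusted p = 0.156 for Usp2 and for Wee1), and adjusted over the list alone 12 were higher and 2 lower. With slide as a block Usp2 and Wee1 passed (adjusted p = 0.0353 each), which sets the MC-LR arrays against control 3. Without control 3, where slide and group coincide, Usp2 (adjusted p = 0.00143), Wee1 (adjusted p = 0.00213) and Ciart (adjusted p = 0.0450) passed. Their ranges over alternatives were 0.00143 to 0.615, 0.00213 to 0.615 and 0.0295 to 0.665. Arntl, which encodes the activator BMAL1, and its partner Clock were the 2 lower ones, with differences of -3.02 ± 0.74 and -1.06 ± 0.27 (log2, SE). Among the 12 higher ones, Ciart, a repressor of the clock, differed by 5.65, Per3 by 2.93, Tef by 2.09, Per2 by 1.79, Cry2 by 1.21 and Hlf by 0.99. Clock, Per2, Per3, Tef, Cry2 and Hlf were singled out after their values were seen. Ciart and Per3 were well above background on 1 and 2 of the 3 control arrays. Under normexp the log2 differences were 0.55 for Wee1, 3.36 for Usp2, 2.01 for Ciart, 1.19 for Per3 and -2.17 for Arntl. The values with slide as a block were 2.97 for Usp2, 3.27 for Ciart, 1.68 for Per3, 1.26 for Tef, 1.09 for Per2, 0.82 for Cry2, 1.14 for Hlf, -1.83 for Arntl and -0.64 for Clock. Controls differed among themselves along the same direction. Arntl stood at 10.39, 9.56 and 8.19 in controls 1, 2 and 3, against 5.61, 5.84 and 7.64 in the MC-LR arrays. Ciart stood at 1.19, 1.25 and 4.79 against 8.81, 8.55 and 6.83. Within slide 2 the list's median difference was 0.93, and with slide as a block its adjusted p was 9.96e-05 (range over the alternatives with the preset correlation 5.70e-08 to 0.000454).

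**Figure D1:**
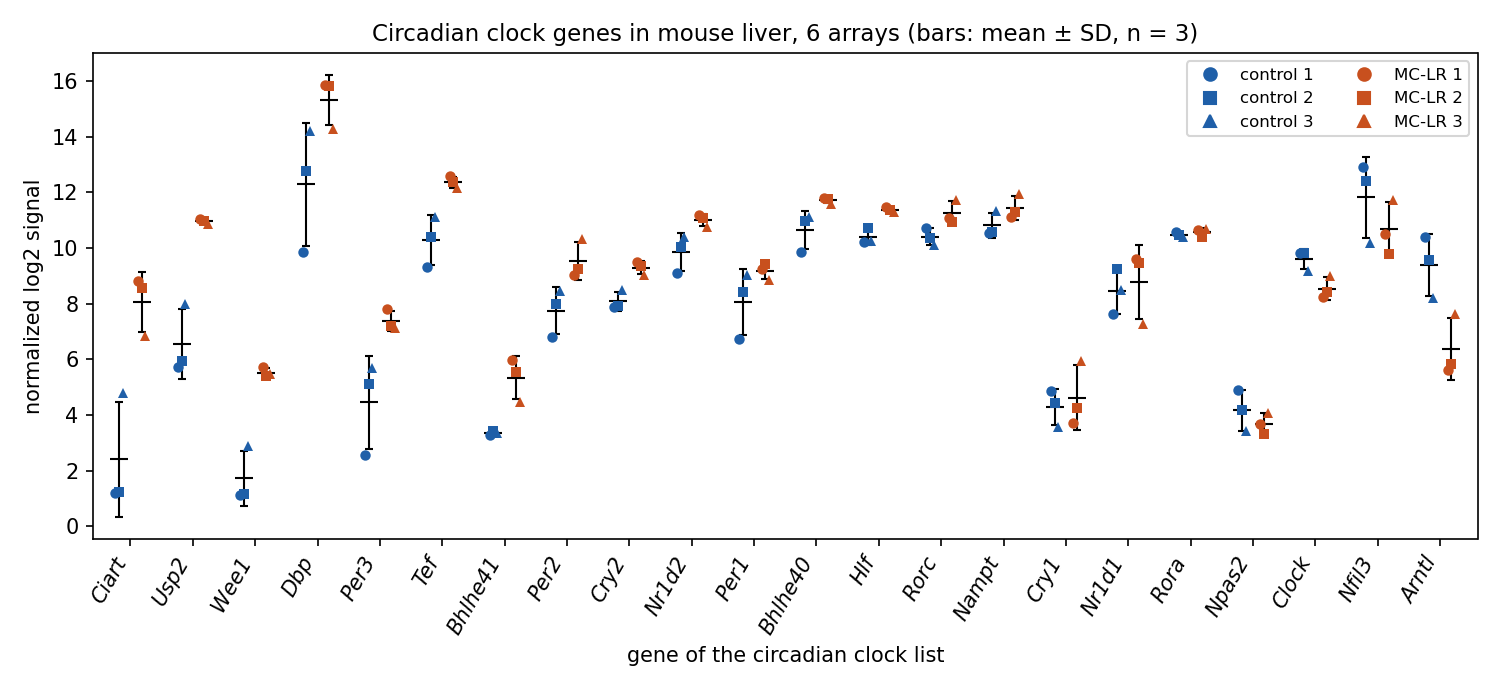
Normalized log2 signal (vertical axis) of the 22 genes of the circadian clock list (horizontal axis, by log2 difference) in each of the 3 control and 3 MC-LR arrays, with the group mean ± SD as bars. The MC-LR arrays lie above the controls for genes such as Ciart and Usp2 and below them for Arntl, where control 3 (8.19) and MC-LR 3 (7.64) lie closest together.

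Drug-metabolising enzymes were higher as a group with MC-LR. Over 36 genes of cytochrome P450 families 1 to 3 and their electron donor, 25 lay above 0 with a median log2 difference of 0.15 (camera, adjusted p = 0.00171, and adjusted p = 0.647 with an estimated correlation). Adjusted over the list alone, 6 were higher and 0 lower, while over all genes 0 passed. Without control 3, with slide and group then coinciding, Cyp2a4 passed (adjusted p = 0.0473, range over its alternatives 0.0302 to 0.665). Cyp2a4, a steroid 15-alpha-hydroxylase, stood at 15.93 ± 0.62 in controls and 17.39 ± 0.04 with MC-LR (log2, mean ± SD, n = 3), 2.74-fold. Cyp2e1, an ethanol-inducible enzyme, stood at 15.79 ± 0.13 and 16.36 ± 0.01, 1.49-fold. The other 4, named after their values were seen, were Cyp2a5 (2.25-fold), Cyp2b9 (2.52-fold), Cyp2b13 (2.54-fold) and Por (2.36-fold), the electron donor of microsomal P450 enzymes. Phase II conjugation enzymes had a median difference of 0.26 over 22 genes (adjusted p = 0.00461, and adjusted p = 0.647 with an estimated correlation), with Ugt2b34 at 0.41 and Ugt2b38 at 0.39. Set in effect against control 3, with slide as a block, the log2 difference fell from 1.45 to 0.80 for Cyp2a4, from 1.17 to 0.55 for Cyp2a5, from 1.24 to 0.75 for Por and from 0.41 to 0.21 for Ugt2b34. It rose from 0.58 to 0.72 for Cyp2e1, from 1.33 to 2.00 for Cyp2b9 and from 1.35 to 1.90 for Cyp2b13. Within slide 2 the medians were 0.28 for the P450 list and 0.22 for the conjugation list. With slide as a block the call of the conjugation list ended (adjusted p = 0.0672, range over its alternatives 0.000247 to 0.0759), while that of the P450 list did not (adjusted p = 0.000184, range 1.69e-05 to 0.0345).

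Genes whose liver expression differs by sex moved with both lists on the higher side, in these male mice. Of 23 female-biased genes, 6 were higher adjusted over the list alone and 0 lower, with 0 over all genes and a median difference of 0.30 (camera, adjusted p = 0.00876, and adjusted p = 0.647 with an estimated correlation). Among them were Acot3, an acyl-CoA thioesterase (log2 difference 3.36 ± 0.68, SE), Cyp2a4, Cyp2b9, Cyp2b13 and Fmo2, a flavin monooxygenase (2.13-fold). Acot3 was well above background on 2 of the 3 control arrays, and its difference under normexp was 1.22. Fmo2 was named after its values were seen. Acot3 differed by 4.76 with slide as a block, and Fmo2 by 0.62 against 1.09 without it. Cyp2a4, Cyp2b9 and Cyp2b13 also belong to the P450 list. Male-biased genes had a median difference of 0.18 over 22 genes (adjusted p = 0.0227, and adjusted p = 0.708 with an estimated correlation), with Cyp4a12b at 0.39 and Ugt2b38 at 0.39. Control 3 differed from the mean of controls 1 and 2 by a median of -0.42 over the male-biased list and 0.11 over the female-biased list. Their medians within slide 2 were 0.56 and 0.55, and without control 3, where slide and group coincide, 0.03 and 0.49. The call of the male-biased list ended without control 3 (adjusted p = 0.639), MC-LR 1 (adjusted p = 0.0965) or MC-LR 3 (adjusted p = 0.171), with a range over its alternatives of 5.62e-06 to 0.639. That of the female-biased list ended without MC-LR 2 (adjusted p = 0.140) and with slide as a block (adjusted p = 0.155, range 0.000497 to 0.155).

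Genes of oxidative phosphorylation, of the pericentral zone of the liver lobule and of fatty acid and triglyceride synthesis were higher as groups. Over 41 genes of oxidative phosphorylation, 32 lay above 0, with a median of 0.12 (camera, adjusted p = 0.00171, and adjusted p = 0.647 with an estimated correlation). Uqcrb, a complex III subunit, differed by 0.41. Pericentral genes had a median of 0.23 over 24 genes, with Cyp2e1 the only member to pass adjusted over the list alone and the Wnt target Axin2 at 0.54 (0.81 with slide as a block). Fatty acid and triglyceride synthesis genes had a median of 0.16 over 27 genes, with Thrsp the only member to pass adjusted over the list alone and the triglyceride-forming enzyme Dgat2 at 0.38. Both lists passed camera (adjusted p = 0.0364 and adjusted p = 0.0386) but had an adjusted p = 0.647 with an estimated correlation. The medians within slide 2 were 0.13, 0.42 and 0.17 for the 3 lists in this order. Without control 3, where slide and group coincide, they were 0.11, 0.06 and 0.23. The pericentral call ended without control 3 (adjusted p = 0.224), MC-LR 1 (adjusted p = 0.0599) or MC-LR 2 (adjusted p = 0.130), with a range over its alternatives of 0.000644 to 0.224. The call of the synthesis list ended with slide as a block (adjusted p = 0.173) and without control 2 (adjusted p = 0.192), control 3 (adjusted p = 0.145), MC-LR 1 (adjusted p = 0.149) or MC-LR 2 (adjusted p = 0.215), with a range of 0.00168 to 0.215.

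Genes of protein folding and the acute phase were lower as groups with MC-LR. Over 30 genes of the unfolded protein and integrated stress responses, 25 lay below 0, with a median log2 difference of -0.27 (camera, adjusted p = 0.000157, and adjusted p = 0.647 with an estimated correlation). Over 28 hepatic acute phase genes 21 lay below 0, with a median of -0.25 (adjusted p = 0.000732, and adjusted p = 0.647 with an estimated correlation). In both lists 0 members passed over all genes or adjusted over the list alone. Manf, an endoplasmic reticulum stress-induced factor, differed by -0.79 ± 0.18 (SE) and Pdia4, a disulphide isomerase, by -0.46 ± 0.10. Lbp, which binds bacterial lipopolysaccharide, differed by -0.85 ± 0.21 and Il1rn, the interleukin-1 receptor antagonist, by -1.15 ± 0.29. Endothelial markers had a median of -0.25 over 24 genes (adjusted p = 0.00243, and adjusted p = 0.647 with an estimated correlation), with Pecam1 (-0.54) lower adjusted over the list alone and Cdh5 at -0.44. Blood cell markers had a median of -0.26 over 15 genes (adjusted p = 0.0478, and adjusted p = 0.647 with an estimated correlation), with Ppbp, a platelet chemokine, at -1.05 and Klf1, an erythroid factor, at 1.02. Across the alternatives Pecam1 ranged from -0.59 to -0.32, Cdh5 from -0.57 to -0.32, Ppbp from -1.32 to -0.75 and Klf1 from 0.58 to 1.31. Within slide 2 the medians were -0.35 for protein folding, -0.20 for the acute phase, 0.02 for endothelial and -0.02 for blood cell markers. The endothelial call ended with slide as a block (adjusted p = 0.943, range over its alternatives 0.000147 to 0.943). The blood cell call ended with slide as a block (adjusted p = 0.680, range 0.00551 to 0.680) and without control 2 (adjusted p = 0.160), MC-LR 1 (adjusted p = 0.0570), MC-LR 2 (adjusted p = 0.0707) or MC-LR 3 (adjusted p = 0.225). It also ended with slide as a random block (adjusted p = 0.158), with no filter on dim probes (adjusted p = 0.0896), with the strict filter (adjusted p = 0.0561) and under 75th percentile scaling (adjusted p = 0.0501).

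Cytoskeletal, p53, interferon and ribosomal genes were lower as well by camera, with an adjusted p = 0.647 with an estimated correlation for each of the 4 lists. Over 35 cytoskeletal genes the median difference was -0.28 (camera, adjusted p = 0.000443), and adjusted over the list alone the tubulins Tubb2a and Tuba4a (-0.65 ± 0.11, log2, SE) were lower. Over 29 p53 target and DNA damage genes it was -0.20 (adjusted p = 0.00309), with Cdkn1a, the cell cycle inhibitor p21 (-1.91 ± 0.34), and Fas, a death receptor (-0.63 ± 0.13), as the 2 genes lower adjusted over the list alone. Over 36 interferon response genes it was -0.36 (adjusted p = 0.000529), with Mx2 (-0.70 ± 0.12) lower adjusted over the list alone and Dhx58 at -0.68. Over 52 cytosolic ribosomal proteins it was -0.09 (adjusted p = 0.00171), with Rps14 at -0.27 and Rps28 at -0.26 (its 3 other probes at -0.11, -0.25 and 0.17). The direction of this list turned under 75th percentile and median scaling. Its named members kept their direction in the alternatives, with -0.32 to -0.13 for Rps14 and -0.28 to -0.06 for Rps28. In each of the 4 lists 0 members passed over all genes. Within slide 2 the medians were -0.70 for the cytoskeletal, -0.37 for the p53, -0.88 for the interferon and -0.18 for the ribosomal list. Control 3 stood above the mean of controls 1 and 2 by medians of 0.58, 0.23, 0.86 and 0.10. Among the named members, control 3 differed from that mean by -0.34 for Tubb2a, -0.76 for Cdkn1a, -0.17 for Mx2 and -0.03 for Fas, and by 0.07 for Tuba4a, 0.12 for Dhx58, 0.07 for Rps14 and 0.01 for Rps28. All 4 calls ended without control 3, with an adjusted p of 0.217 for the cytoskeletal (range over its alternatives 2.65e-09 to 0.217), 0.207 for the p53 (9.09e-05 to 0.207), 0.741 for the interferon (2.70e-13 to 0.741) and 0.217 for the ribosomal list (4.42e-06 to 0.601).

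Cytokine, matrix, dedifferentiation and immediate early genes and the markers of neutrophils and macrophages were also lower by camera. With an estimated correlation their adjusted p was 0.673 for cytokines, 0.745 for the matrix and macrophage lists, 0.653 for dedifferentiation and 0.647 for neutrophil markers and immediate early genes. The estimates were 0.52 for the cytokine and matrix lists, 0.58 for neutrophil and 0.57 for macrophage markers. For dedifferentiation and immediate early genes they were 0.38 and 0.11, so the preset 0.01 makes the p-values of these lists too small. The median log2 differences were -0.28 over 37 cytokine, chemokine and NF-kB target genes (adjusted p = 0.00243), -0.49 over 14 neutrophil markers (adjusted p = 0.00800) and -0.30 over 28 macrophage and Kupffer cell markers (adjusted p = 0.0343). They were -0.13 over 43 matrix and fibrosis genes (adjusted p = 0.0190), -0.31 over 28 dedifferentiation and tumour-associated genes (adjusted p = 0.0132) and -0.32 over 27 immediate early genes (adjusted p = 0.0382). No member passed over all genes or adjusted over the list alone. Nfkb1, a subunit of the transcription factor, differed by -0.54 with the probe used, by -0.03, -0.20 and 0.04 with its 3 other probes and by -0.18 with the mean of its probes. Lcn2, a siderophore-binding protein, differed by -1.31 and Mmp14, a matrix protease, by -0.81. Sox9, a bile duct and progenitor factor, differed by -0.73, Scara5, a ferritin receptor, by -0.78, and Btg2, an antiproliferative factor, by -0.65. Hdc, the histamine-forming enzyme of the neutrophil list, differed by -0.52. Against these directions, Gpnmb, a macrophage glycoprotein, differed by 1.10 (0.57 to 1.39 over its alternatives) and the iron exporter Slc40a1 by 0.46. Likewise, the protease inhibitor Timp3 differed by 0.74 and the small Maf factor Maff by 1.09. The differences with slide as a block were 0.27 for Slc40a1, 0.37 for Timp3, 0.47 for Maff, -0.51 for Scara5 and -1.06 for Btg2. Without control 3, where slide and group coincide, Timp3 passed over all genes (adjusted p = 0.0473, range over its alternatives 0.0295 to 0.671). Control 3 lay above the mean of controls 1 and 2 by a median of 1.14 over the cytokine list, 0.79 over neutrophil, 0.77 over macrophage, 0.64 over matrix, 0.83 over dedifferentiation and 0.50 over immediate early genes. Within slide 2 the 6 medians, in the same order, were -1.05, -0.98, -0.84, -0.58, -0.78 and -0.58. All 6 calls ended without control 3, with an adjusted p of 0.741 for cytokines (range over alternatives 2.81e-19 to 0.741), 0.329 for neutrophils (5.08e-06 to 0.329), and 0.9978 for macrophages (1.94e-08 to 0.9978). It was 0.741 for matrix (2.65e-09 to 0.758), 0.648 for dedifferentiation (5.08e-06 to 0.648) and 0.661 for immediate early genes (7.10e-05 to 0.661). The cytokine, macrophage and matrix lists then turned higher. Without MC-LR 1 the calls of the neutrophil (adjusted p = 0.0528), macrophage (adjusted p = 0.347), matrix (adjusted p = 0.118), dedifferentiation and immediate early lists (adjusted p = 0.0599 each) also ended. Without MC-LR 3 the same held for those of the neutrophil (adjusted p = 0.0750), matrix (adjusted p = 0.170), dedifferentiation (adjusted p = 0.324) and immediate early lists (adjusted p = 0.0562), and for the last also without MC-LR 2 (adjusted p = 0.0707). The macrophage call also ended with no filter on dim probes (adjusted p = 0.0617), the strict filter (adjusted p = 0.0529) and the mean of probes (adjusted p = 0.0640), and the immediate early call with no filter (adjusted p = 0.0709) and the strict filter (adjusted p = 0.0561).

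Markers of lymphocytes were not called. T and NK cell markers had a median of -0.05 over 24 genes (camera, adjusted p = 0.901). The granzyme Gzma differed by 0.61 (0.26 to 0.76 over its alternatives) and the perforin Prf1 by -0.44 (-0.63 to -0.15). B and plasma cell markers had a median of -0.19 over 15 genes (adjusted p = 0.161), with Derl3 at -0.81 (-0.17 with slide as a block) and Mzb1, a plasma cell chaperone, at -0.39 (-0.46 with slide as a block, -0.19 without control 1 and -0.16 without MC-LR 3). With slide as a block, in effect against control 3, both lists passed as lower (adjusted p = 0.00117 and 0.00605). The B cell list also passed with slide as a random block (adjusted p = 0.0466), without control 2 (adjusted p = 0.00871) and without MC-LR 1 (adjusted p = 0.0308). Over the alternatives the adjusted p ranged from 0.00103 to 0.971 for T and NK cells and from 0.00377 to 0.947 for B and plasma cells. Their medians within slide 2 were -0.46 and -0.69, and control 3 lay above the mean of controls 1 and 2 by 0.62 and 0.67.

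**Figure D2:**
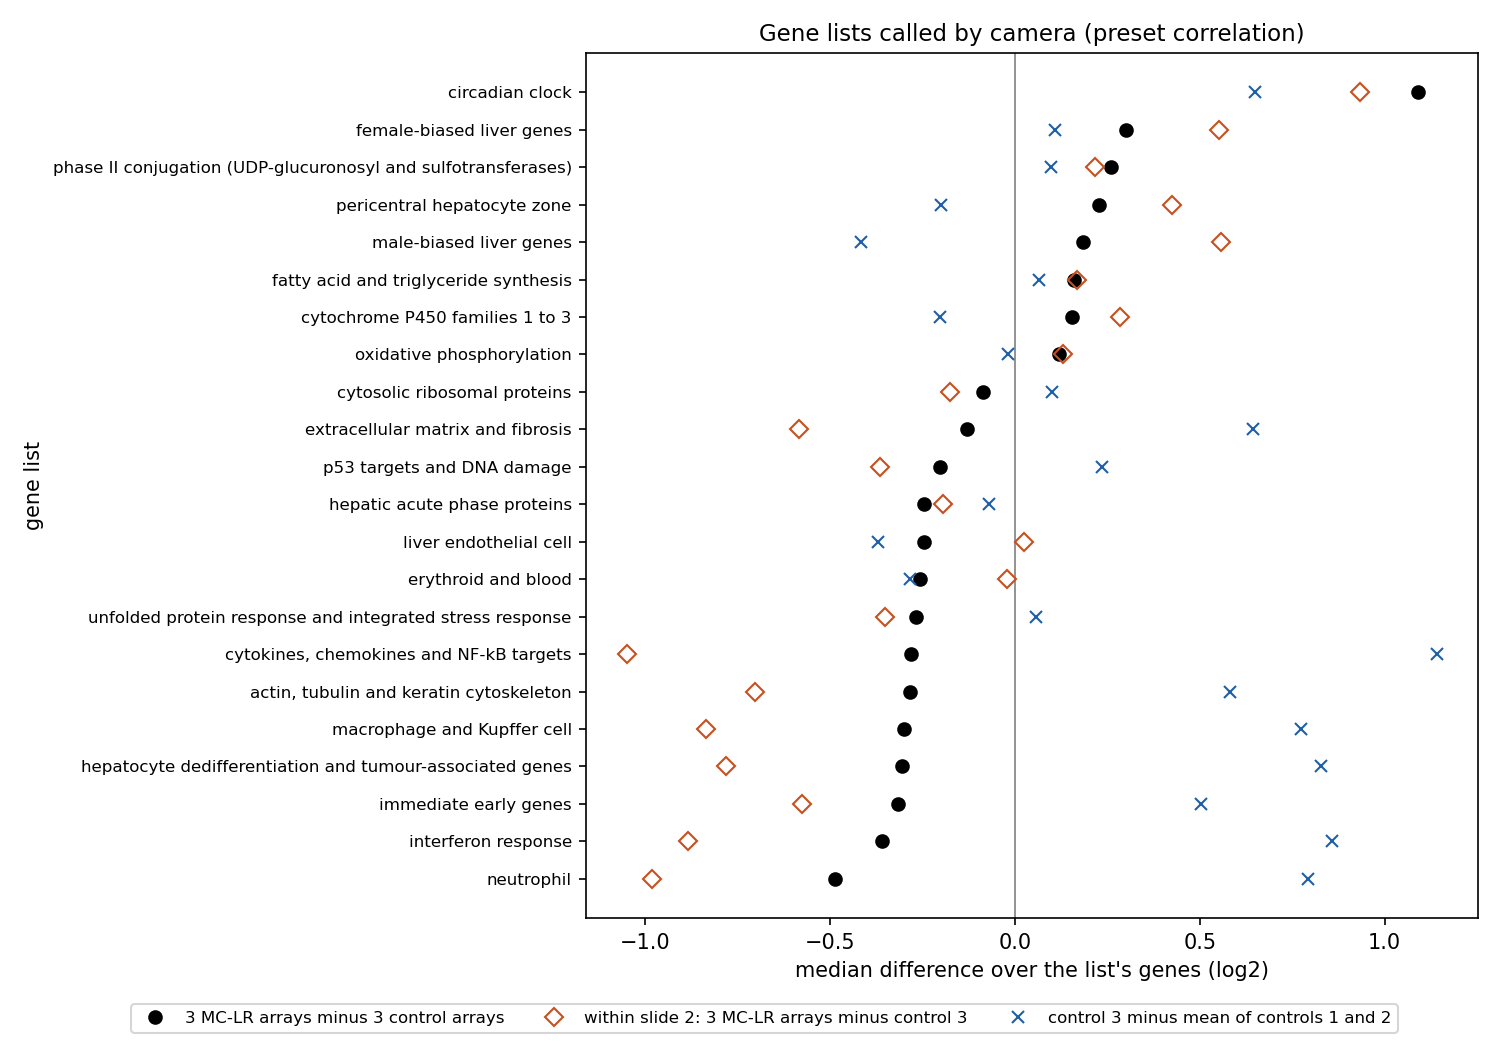
Median log2 difference over the genes of each of the 22 lists that passed camera with the preset correlation (vertical axis, list; horizontal axis, log2 difference): filled circles, 3 MC-LR minus 3 control arrays; diamonds, MC-LR minus control 3 within slide 2; crosses, control 3 minus the mean of controls 1 and 2. The clock list lies highest at 1.09, and for the cytokine list the cross lies at 1.14 and the diamond at -1.05.

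The targets and uptake routes of MC-LR did not pass limma or camera over all arrays. The catalytic subunits of protein phosphatase 1, Ppp1ca, Ppp1cb and Ppp1cc, differed by -0.10 ± 0.10, -0.19 ± 0.12 and -0.05 ± 0.10, and those of protein phosphatase 2A, Ppp2ca and Ppp2cb, by -0.06 ± 0.09 and 0.07 ± 0.10 (log2, SE, n = 3 per group), with adjusted p from 0.538 to 0.877 by limma. The values of Ppp1cc and Ppp2ca turned above 0 under median scaling, that of Ppp1cc also without control 3 and that of Ppp2ca with the mean of probes, while that of Ppp2cb turned below 0 with slide as a block. Other probes lay at 0.33 and 0.02 for Ppp2ca, -0.19 for Ppp1cc and 0.004 for Ppp2cb. Over 21 phosphatase subunits and regulators the median was -0.06 (camera, adjusted p = 0.914), with Ppp2r5a at 0.23 (other probes 0.01 and 0.07) and Igbp1 at 0.23 (other probe -0.09). The list did pass fry for change in either direction (adjusted p = 0.0459), which asks whether members changed at all and not whether they changed more than other genes. The uptake transporter Slco1b2 differed by 0.23 ± 0.14 (adjusted p = 0.524) and Slco1a4 by 0.06 ± 0.43 (adjusted p = 0.968), which lay at 0.36 and -0.91 with slide as a block. Slco1a1, a male-biased uptake transporter, stood at 10.54, 10.47 and 4.69 in controls 1, 2 and 3 and at 11.20, 9.56 and 10.81 in the MC-LR arrays, a difference of 1.96 ± 1.63 (adjusted p = 0.643) that was 1.24 under normexp, 0.02 without control 3 and 5.83 with slide as a block, so it rests on control 3. Over 18 uptake and export genes the median was 0.22 (camera, adjusted p = 0.0797), with the efflux pump Abcb1a at 1.34 (0.40 under normexp, 0.81 with slide as a block) and the sterol exporter Abcg5 at 0.74 (1.14 with slide as a block). The list passed with slide as a block (adjusted p = 0.0149), under both scalings and without control 2 (adjusted p = 0.0193). Over 23 genes of glutathione conjugation and synthesis it was 0.07 (adjusted p = 0.160), with Gstt2 (0.77 ± 0.12) the only member higher adjusted over the list alone and Gstt3 at 0.55 (0.93 with slide as a block). That list passed under 75th percentile scaling (adjusted p = 0.00821) and median scaling (adjusted p = 0.00912). Over 27 NRF2 target and antioxidant genes it was -0.02 (adjusted p = 0.823), with Gclm at 0.24 (other probe -0.15) and Gclc at -0.41 (-0.19 with slide as a block), the regulatory and catalytic subunits of the enzyme that starts glutathione synthesis. This list passed as lower with slide as a block (adjusted p = 0.00792).

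**Figure D3:**
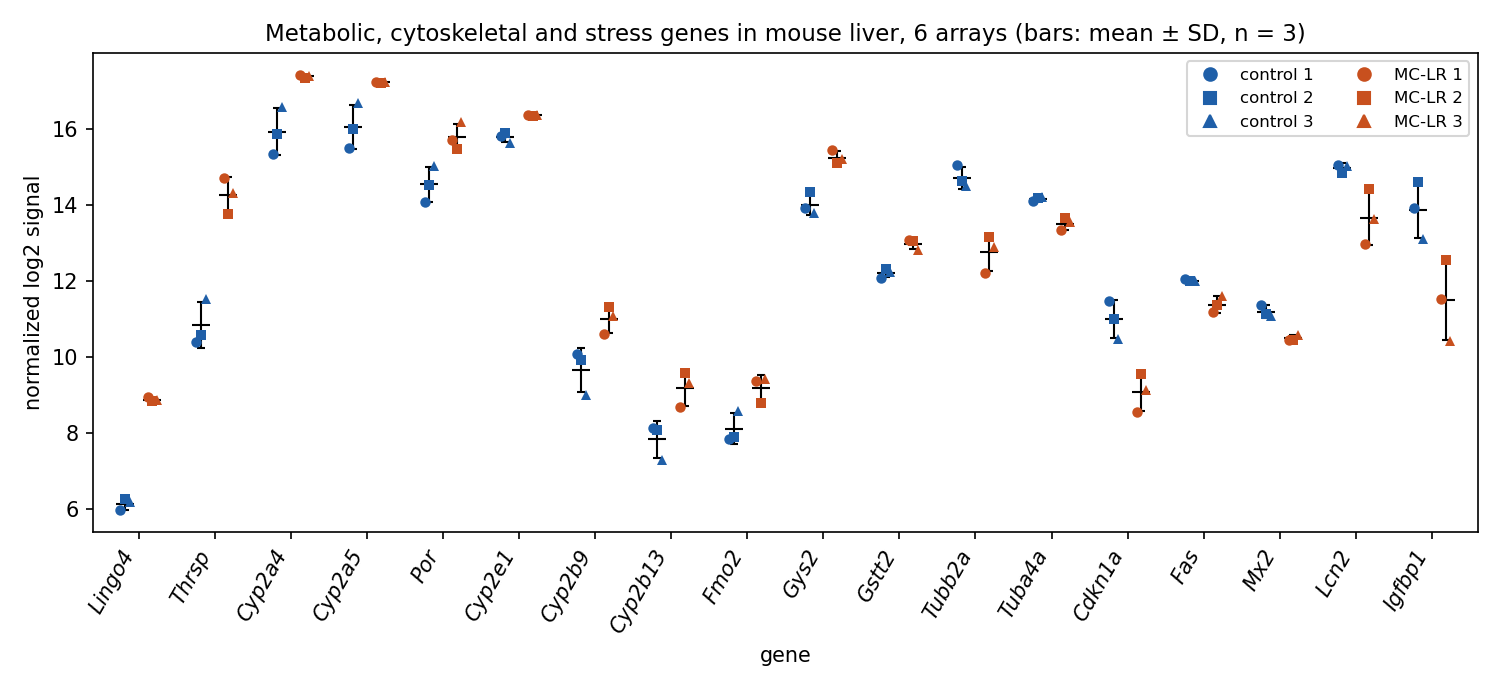
Normalized log2 signal (vertical axis) of 18 genes of drug metabolism, glucose and lipid metabolism, the cytoskeleton and stress (horizontal axis) in each of the 3 control and 3 MC-LR arrays, with the group mean ± SD as bars. Lingo4 (6.15 against 8.88) alone among these passed over all genes, and the groups do not overlap for Cyp2a4 (15.93 against 17.39) or Tubb2a (14.72 against 12.76).

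Across all lists, 22 of the 47 tested passed camera with the preset correlation, 8 higher and 14 lower, and 0 with an estimated correlation. With slide as a block 26 passed, 17 of them in the same direction as without it, and 10 passed without control 3, where slide and group coincide.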

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

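The camera calls of 5 lists (circadian clock, protein folding stress, acute phase, oxidative phosphorylation and cytochrome P450) held in the same direction in all 19 alternatives that keep the preset correlation, while with an estimated correlation 0 lists were called (clock, adjusted p = 0.647). Their highest adjusted p over those alternatives was 0.0494 for acute phase and 0.0484 for oxidative phosphorylation, just under the threshold. It was 0.0161 for protein folding, 0.0345 for cytochrome P450 and 0.000454 for the clock. With fry, 0 were called in one direction (clock, adjusted p = 0.0848) and 10 in either direction, 4 of them (phosphatases, glycolysis, adipocyte markers and nuclear receptors) not called by camera. Camera with the estimate and fry both use the correlation between genes in these arrays, which the preset value does not. Estimates were 0.05 for the clock and P450 lists, 0.25 for acute phase, 0.28 for protein folding and 0.29 for oxidative phosphorylation. They were 0.61 for interferon and 0.40 for cytoskeletal genes. Where genes move together more than the preset 0.01 allows, the preset p-value is too small. The correlation is not the whole difference, since camera p-values also rose where the estimate lay near or below 0.01. Camera refers its statistic to the 4 residual degrees of freedom with the estimate, and to far more with the preset value. Its p-values therefore rise even at an equal correlation. For glycolysis (estimate 0.011) the unadjusted camera p went from 0.0742 to 0.151, for hepatocyte markers (-0.0002) from 0.0340 to 0.0784. The clock list had an unadjusted camera p of 0.0165 with the estimate, and 0.647 was the smallest adjusted p of any list. Of 3 genes changed (all higher), 1 was called under 75th percentile scaling, median scaling, normexp and the strict filter on dim probes, and 5 (all higher) with no filter. The strict filter removes genes that are dim in a group. The normexp setting adds an offset of 50 to each signal, which by construction draws the log2 differences of dim probes toward 0. The cause of the other changes was not tested. Slide as a fixed block gave 15 genes (9 higher, 6 lower), in effect the MC-LR arrays against control 3, and as a random block 1 lower gene among 4. Slide 2 alone gave 0 genes changed and 0 higher, with 1 control array left that is assumed to vary like the others. Array weights gave 888 genes changed (548 genes higher and 340 genes lower) and 10 lists, with control 3 at a weight of 0.26. An unadjusted p under 0.05 with a fold of 2 gave 320 genes (214 higher, 106 lower). Without each array in turn, 1 to 50 genes changed (1 to 38 higher, 0 to 12 lower) and 10 to 27 lists were called. The high gene counts and the 10 lists came without control 3, where slide and group coincide, and the 1 gene without MC-LR 1. Genes at an unadjusted p under 0.05 were 58.4% higher, against 68.5% under median scaling, 49.6% with slide as a fixed block, 49.0% within slide 2, 51.2% without control 3 and 50.8% with array weights.

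Ribosomal proteins turned higher under 75th percentile scaling (adjusted p = 0.601) and median scaling (adjusted p = 0.285), and without control 3 the cytokine, matrix and macrophage lists turned higher (adjusted p = 0.741, 0.741 and 0.9978), with lowest values of 2.39e-07, 7.88e-05 and 0.00110 when another array was left out. The cause was not tested for the scalings. Of the list calls, 10 of the 14 lower and 3 of the 8 higher ended without control 3. Without MC-LR 1, 9 list calls ended, with 5 without MC-LR 2 and 6 without MC-LR 3. Of 93 genes run under each alternative, 15 of them chosen after their values were seen, 80 had an unadjusted p under 0.05, and 0 of these changed direction in an alternative that measured them. The naming rule itself picks genes by groups that lie apart or by small p in these arrays. Where the groups lie apart, leaving out an array or blocking on slide cannot turn the direction. That 0 is therefore largely set by the selection.

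The replicate number as a block gave 0 genes changed and 0 higher (limma, 1833 at an unadjusted p under 0.05), and 22 lists, with an adjusted p of 0.0876 for Cst10, 0.303 for Lingo4 and 0.382 for 2610034B04Rik. The shared numbers showed no pairing of the mice: deviations from the group means correlated across genes at 0.186, -0.324 and -0.197 for replicates 1, 2 and 3, and control 2 correlated best with MC-LR 3. With 3 arrays per group and the controls on both slides, this cannot exclude a pairing. Signal over background limits Cst10, whose controls lie near the floor.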

Other observations

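The tests of the clock genes by slide and by collection, of the lists without control 3 and of the markers in control 3 were chosen after the results were seen, as was the split test of the gene count, while those of the gene lists and the clock list, and leaving out each array, were set beforehand.

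Several lists that camera did not call held members that were higher or lower adjusted over the list alone, with 0 past the threshold over all genes. In glycolysis and gluconeogenesis (31 genes, camera adjusted p = 0.120, fry in either direction 0.0279), Gys2, the liver glycogen synthase, differed by 1.23 ± 0.18 (log2, SE), Slc37a4, the glucose-6-phosphate transporter, by 0.71 ± 0.15 and Slc2a2, the hepatocyte glucose transporter, by 0.98 ± 0.22. In bile acid synthesis (18 genes, adjusted p = 0.984, with a median of 0.06 but a test direction of lower), Nr0b2, a repressor of that pathway, differed by -0.98 ± 0.22 and Acox2, a bile acid side-chain oxidase, by -0.56 ± 0.12. In cell cycle and proliferation (38 genes, adjusted p = 0.134), Ccne2, a G1 cyclin, differed by 1.87 ± 0.18 and Tk1, a thymidine kinase, by 1.16 ± 0.22, and Ccne2 was well above background on 1 of the 3 control arrays. Under normexp the Ccne2 difference was 0.33, and without control 3, where slide and group coincide, the gene passed over all genes (adjusted p = 0.0413, range over its alternatives 0.0188 to 0.615). The glycolysis list passed as higher under 75th percentile scaling (adjusted p = 0.0148), median scaling (adjusted p = 0.0195) and with every probe (adjusted p = 0.0311), with a range of 0.0148 to 0.991. The cell cycle list passed as higher without MC-LR 1 (adjusted p = 0.0385) and without MC-LR 3 (adjusted p = 0.000963), with a range of 0.000963 to 0.732. With slide as a block both lists had a test direction of lower (adjusted p = 0.961 and 0.703). Slc2a2 was named after its values were seen. Outside all lists, and also named after their values were seen, Dhrs9, a retinol dehydrogenase, stood at 7.28, 7.46 and 7.76 in controls 1, 2 and 3 and at 5.54, 5.66 and 5.45 in the MC-LR arrays (adjusted p = 0.0584, limma). It passed with slide as a fixed block (adjusted p = 0.0353) or random block (adjusted p = 0.0440) and, like Upp2, without control 3 (adjusted p = 0.0298), where slide and group coincide, with a range of 0.00976 to 0.549, and differed by -0.96 under normexp. Upp2, a uridine phosphorylase, stood at 8.52, 8.21 and 10.25 against 12.68, 11.88 and 12.19 (adjusted p = 0.209), with an adjusted p of 0.0321 without control 3 (range 0.0295 to 0.665) and a log2 difference of 2.00 with slide as a block against 3.26 without it.

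Clock genes of opposite phase differed in opposite directions between the groups, although 0 members of the clock list passed over all genes and the list had an adjusted p = 0.647 with an estimated correlation. Over 17 of them, split by textbook regulation after the results were seen (12 driven through E-box or D-box elements, 5 through RORE elements), 16 lay above 0 for the former or below 0 for the latter, with a median of 1.79 on the log2 scale, and 11 of these passed adjusted over the list alone. Within slide 2 the median was 1.10 (quartiles 0.29 and 1.83) with 14 of 17 genes in that direction, but that value rests on control 3 as the only control, so a slide difference stays open as a part of it. The hour of collection may account for part of it. A score was the mean of the E-box or D-box genes minus that of the RORE genes. Each gene was centred on its mean over the 6 arrays, so that only steps between arrays count. The score was -3.47, -1.90 and 0.11 in controls 1, 2 and 3 and 2.48, 2.35 and 0.44 in the MC-LR arrays. The step from controls 1 and 2 to control 3 was 2.80, against a group difference of 3.51 and a difference of 1.64 within slide 2. That step is 79.8% of the group difference but not a share of it, since control 3 enters both. It also runs from slide 1 to slide 2, so slide may account for it as well as the hour. Hours are not given in the labels used here, so an hour that differed between groups and an effect of MC-LR on the clock cannot be told apart, and either is a hypothesis. The missing hours limit the differences of the other lists and genes in the same way. Whether these follow the clock genes was not tested.

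Of the 14 lists called lower with MC-LR, 10 lost their call without control 3, while 14 stayed called without control 1 and 13 without control 2. For 5 of the 10 the call stayed without each other array, and without control 3 their medians were 0.01 (cytokine), -0.05 (interferon), -0.11 (cytoskeletal), -0.18 (p53) and -0.05 (ribosomal), against -0.28, -0.36, -0.28, -0.20 and -0.09 with it. The ribosomal call also ended and turned under 75th percentile and median scaling, and for the other 5 of the 10 (neutrophil, macrophage, matrix, dedifferentiation and immediate early) the call also ended without an MC-LR array. Since slide and group coincide without control 3, a source in control 3 and a slide difference cannot be told apart for 9 of these lists, while for p53 the median hardly changed, so its lost call is no support for control 3 as the source. The remaining 4 stayed called lower without control 3, so their calls do not need that array. Slide and group then coincide, however, so a slide difference may hold these calls. With slide as a block, in effect against control 3, the endothelial and blood cell calls ended (camera, adjusted p = 0.943 and 0.680). The protein folding and acute phase calls did not (camera, adjusted p = 0.000486 and 0.0494). The former setting rests on slide and the latter on control 3, so neither source is decided for these 4 lists.

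In control 3, 100 markers of macrophages, neutrophils, T, B and bile duct cells lay above controls 1 and 2 by a median of 0.72, stellate cell markers by 0.18 (17 of 24 above 0) and endothelial markers by -0.37. The endothelial markers lay -1.09 from the 100 (permutation p = 1e-05 over genes, the smallest these permutations can give, and genes are not independent), but part of this may come from slide, since they also lay at -0.36 in the MC-LR arrays. Against the MC-LR arrays on the same slide, control 3 lay at 0.72 over the 100 markers, 0.22 over stellate and -0.02 over endothelial markers. The difference between the first and the last was -0.75. The markers moved apart in both comparisons, but both rest on control 3 alone. The 100 markers were pooled after the results were seen, without the stellate markers. A lower share of hepatocytes in control 3 is therefore not decided. Over the 100 markers the MC-LR arrays lay 0.020 (quartiles -0.20 and 0.25) from controls 1 and 2, but they belong to the other group and control 3 is the only control on slide 2. A slide difference and a difference of this mouse, such as inflammation, therefore cannot be told apart.

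The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real groups gave 3 genes at an adjusted p under 0.05 and each other split gave 0, so 1 split, the real one, reached that count. The split of controls 1 and 2 with MC-LR 3 from the rest, which keeps slide 1 together, gave 2508 genes at an unadjusted p under 0.05 against 2434, and within slide 2 the count was 2308. For gene lists, 3 of the 10 splits called as many as the real 22, and the highest of the others, which parts the slide 1 arrays, called 28. For the clock list the real split gave an adjusted p of 1.18e-05, reached by 1 split, the real one, and the smallest of the others was 0.0171.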
